A study of Mus musculus with 6 samples.

How the data were processed

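RNA sequencing libraries of total RNA from mouse KP cells were analysed, 3 without and 3 with doxycycline. Per the labels' protocols, cells carried a doxycycline-inducible vector with 1 of 3 hairpins against Npm1, had been selected with puromycin to give 3 stable lines, and were treated with 100 ng/ml doxycycline or left untreated, and RNA was isolated with a column kit. Groups and line numbers were taken from the labels. The deposited values are whole-number read counts per gene, made by the authors, with 1 column per library and no normalization. Per the submitters' processing notes the tools were CASAVA, STAR, Picard, HTSeq, DESeq2, bedtools and R 3.3.0, with the genome build mm10. The annotation release, the strand setting and the versions of the other tools are not given in the sources used here. Counts of genes that overlap on opposite strands can therefore not be told apart, and a read that aligns to more than 1 place is not counted for any gene, which lowers genes with near-identical copies.

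The files held 48526 gene identifiers and 5 rows that name no gene, which were left out of library sizes and tests. These rows held 43.8% to 47.7% of all reads. Gene symbols were found for 48058 identifiers in the GENCODE annotation of the same build, from which transcript lengths, GC content, coordinates and overlaps of exons were also taken. Length and GC content are those of the longest annotated transcript of each gene, which need not be the one expressed. Copies of Npm1 were sought with blastn 2.17.0. The counts in genes were 26756552, 25270163 and 26391521 in lines 3, 4 and 5 without doxycycline and 24391198, 27341036 and 25193115 with it. A floor of 3 counts corresponds to 0.11 to 0.123 CPM in these libraries.

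The counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test of doxycycline against none, Benjamini-Hochberg adjustment). CPM values were computed with TMM-scaled library sizes. Standard errors are the size of the log2 fold change divided by the square root of F. The biological coefficient of variation was 18.0%. Since the spread was that between 3 lines with different hairpins, the p-values measure whether a difference exceeded the spread between lines, and nothing shows how separate cultures of the same line would differ. Lists of genes were tested with camera in limma 3.58.1 when at least 5 members were tested. Ratios of genes with 1 to 3 counts in a group were given with exact binomial intervals at 95%, and genes with 0 counts with a bound against 3 counts over the group. Ratios within a line were computed after adding 0.5 to each CPM. The lines were compared by an F test of the line terms in a model with doxycycline and line.

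Line numbers pair the samples, since libraries of the same number come from the same stable line. As a check, deviations from the group means correlated across genes with r = 0.113, 0.174 and 0.033 within lines 3, 4 and 5, and with r = -0.204 to 0.084 between libraries of different lines. The untreated library of line 5 correlated more with the treated library of line 3 (0.084) than with its own (0.033), so the pairing rests on the stable lines and not on this check. The fit without the line as a block was the main one, and the paired fit, with the replicate block, called 243 genes (103 higher, 140 lower), 226 of them among the 332.

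Named genes were chosen by a rule fixed before the data were examined, as were the 24 lists and most alternatives. The rule took Npm1; the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 CPM and the same direction in the 3 lines, passing over genes with only a clone name; up to 4 passing members of each list by smallest p, or otherwise 2 as values; and 6 genes of smallest p for the lines. Of the genes the rule took, 2 are not reported here. Alternatives were RLE scaling, no filter on low counts, the block, each library and each line left out, DESeq2 1.42.0, limma-voom, other thresholds, a minimum log2 fold change of 0.5, an estimated correlation, and fry. After the data were seen, offsets that remove the trend of each library on transcript length and GC content, a minimum of 5 CPM, a fit without macrophage and lymphocyte genes list tests on DESeq2 and limma-voom values, and an estimated correlation in the fits without a library or line and with the offsets were added. So were 6 lists, of macrophage, T lymphocyte, B lymphocyte, mitochondrial ribosomal protein, DNA replication and hemidesmosome and squamous genes.

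The procedures were tested on simulated data with 200 changed genes. For doxycycline against none, edgeR recovered 3% of 67 genes changed 1.5-fold, 49.3% of 67 changed 2-fold and 87.9% of 66 changed 4-fold, with 0 false calls in 14533 genes. On the same simulated counts DESeq2 recovered 17.9%, 68.7% and 90.9% with 15 false calls, and the replicate block 10.4%, 62.7% and 95.5% with 7. The fit with offsets made 1 false call and limma-voom 0. These counts were drawn with the same dispersion in both groups and with no trend on length or GC content. In the real libraries replicates differed more with doxycycline than without it, and the log2 ratio of line 3 had a trend on length. The false calls above are therefore no measure of the error rate of the real calls. The comparison of lines recovered 98% of 200 genes changed 4-fold, with 7 false calls in 14533 genes. This difference was planted alike in both libraries of line 4, and no simulated response to doxycycline differed between lines. The 98% is therefore no measure of what the comparison finds where lines respond differently. A list raised by a log2 value of 0.5 was recovered among 23 lists, with 0 other lists called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called by mistake. In the real libraries the estimated correlation was 0.896 for the cytosolic ribosomal proteins. A planted trend on length went from a Spearman's rho of -0.389 to -0.00831 over 14600 genes.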

Results

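RNA sequencing was used to compare mouse KP cells without and with an induced hairpin against Npm1, the gene of nucleophosmin, an abundant nucleolar protein. KP is the name the labels give the cells, which they do not describe further. The cells had been made into 3 stable lines, each with a vector that expresses a hairpin RNA against Npm1 only when doxycycline, a tetracycline antibiotic, is present. The lines are named here after their hairpins, line 3, line 4 and line 5. Total RNA of each line was sequenced after growth without doxycycline and with 100 ng/ml doxycycline, which gave 6 libraries, 3 per group. The lines stood in for replicates, so that a difference between the groups was set against the spread between lines, and each line had 1 library per condition. No library came from cells with doxycycline and without a hairpin against Npm1, and an effect of the drug itself was therefore not separated from the knockdown. Dates and batches of library preparation or sequencing are not given in the sources used here, so a batch that follows the treatment cannot be told apart from it. The labels name no cell type other than KP in the cultures. The libraries held 24391198 to 27341036 counts in genes, and 14531 genes passed the filter on low counts. Replicates of a group were not duplicates of each other: the chi-square of their counts per degree of freedom over these genes was 7.86 to 22.6 without doxycycline and 35.8 to 108 with it.

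Npm1 (ENSMUSG00000057113; mm10 chromosome 11, 33152287 to 33163206, minus strand, 11 exons in its longest annotated transcript) was lower with doxycycline in all 3 lines. Its level was 1926 ± 75.4 CPM (SD, n = 3) without doxycycline and 237 ± 166 CPM (SD, n = 3) with it. In line 3 it went from 2002 to 67.8 CPM, so that 3.39% remained. In line 4 it went from 1851 to 245 CPM, with 13.2% remaining, and in line 5 from 1924 to 400 CPM, with 20.8% remaining. The log2 fold change was -3.02 (SE 0.49, edgeR quasi-likelihood test, adjusted p = 0.011). A 2-sided exact permutation test of the 6 log2 values gave p = 0.1, the smallest that 3 against 3 libraries allow. The edgeR adjusted p of Npm1 rose to 0.0937 without the untreated library of line 3 and to 0.177 without both libraries of line 4, while the log2 fold change stayed between -3.63 and -2.55 when any library or line was left out. Among processed pseudogenes with sequence like that of Npm1, 3 had enough counts to be tested and all 3 were lower. Gm14681 on chromosome X (66778442 to 66778852), 97.4% identical over 420 aligned bases, went from 10.3 ± 0.865 to 0.938 ± 0.308 CPM (SD, n = 3 each; edgeR adjusted p = 0.000255), and reads of the 2 loci may have been shared.

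**Figure D1:**
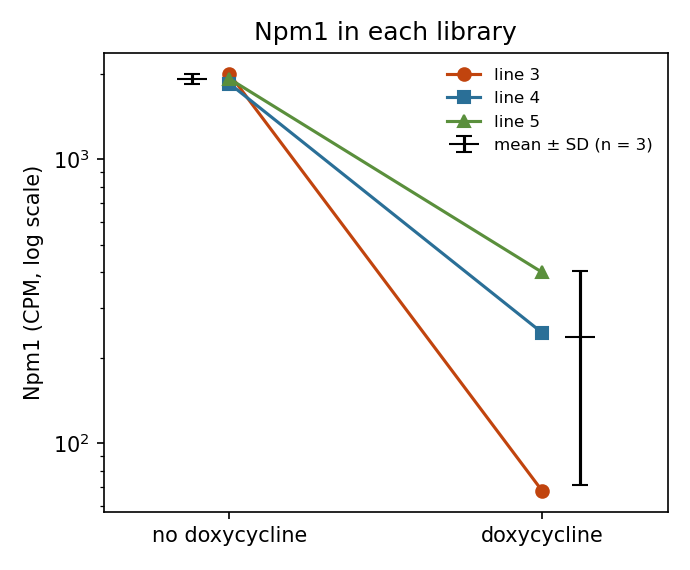
Npm1 level in CPM (log axis) in the 6 libraries, with a line joining the 2 libraries of each stable line and black bars for the group mean ± SD (n = 3). Npm1 fell to 67.8 CPM in line 3, 245 CPM in line 4 and 400 CPM in line 5, from 1851 to 2002 CPM without doxycycline.

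With doxycycline 140 genes were higher and 192 lower, 332 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among genes with at least 5 CPM on average, those with the largest rise were genes of macrophages. Gpnmb, a membrane glycoprotein of macrophages and other phagocytes, was at 0.052 ± 0.0599 CPM (SD, n = 3) without doxycycline and 62.6 ± 32.8 CPM (SD, n = 3) with it. Lyz2, the lysozyme of myeloid cells, went from 8.33 ± 2.22 to 99.0 ± 43.3 CPM (log2 fold change 3.57, SE 0.32, edgeR adjusted p = 0.000525), and its near-identical neighbour Lyz1 can share its reads. Apart from Npm1 and its pseudogene Gm14681, the water and glycerol channel Aqp3 fell most among genes with at least 5 CPM on average, from 45.4 ± 11.1 to 8.73 ± 3.82 CPM (log2 fold change -2.39, SE 0.32, edgeR adjusted p = 0.00389).

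Of the 12 named genes with the largest rise, 11 were genes known from macrophages or from lipid handling in them. Mmp12, the macrophage metalloelastase, had 1 count over the 3 libraries without doxycycline and 1647 over the 3 with it, a ratio of 1680 (95% exact counting interval 301 to 66400). Adgre1, which encodes the macrophage marker F4/80, had 2 and 845 counts, a ratio of 431 (119 to 3560). The signal-regulatory receptor Sirpa rose by a log2 fold change of 6.64 (SE 0.45, edgeR adjusted p = 0.000165). The scavenger receptor Cd36 rose by 5.15 (SE 0.42), lipoprotein lipase (Lpl) by 4.83 (SE 0.41), the pore-forming protein Mpeg1 by 4.79 (SE 0.39) and cathepsin S (Ctss) by 4.77 (SE 0.50), with edgeR adjusted p of 0.000255 to 0.00119 for these last 4. Apoe, the apolipoprotein, went from 5.82 ± 0.911 to 19.6 ± 6.71 CPM (edgeR adjusted p = 0.00531). Csf1r, the receptor for the macrophage growth factor, went from 2.94 ± 0.920 to 9.68 ± 2.67 CPM (edgeR adjusted p = 0.0139). Its exonic bases overlap Hmgxb3 at 15.1%. The remaining gene, Rn7sk, is the small nuclear RNA that holds the elongation factor P-TEFb inactive, and it rose from 18.7 ± 2.43 to 62.2 ± 19.8 CPM (log2 fold change 1.73, SE 0.22, edgeR adjusted p = 0.0027). Many called genes were near absent in the other group: 81 of the 140 higher genes had a mean under 1 CPM without doxycycline, and 88 of the 192 lower genes a mean under 1 CPM with it.

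Genes of blood cells moved in both directions. Of the 17 tested leukocyte markers, 5 rose and 6 fell over all genes tested (5 and 8 adjusted over the list alone), and 6 did not pass. T lymphocyte markers were among those that fell. Cd3e, a chain of the T cell receptor complex, had 105 counts without doxycycline and 2 with it, a ratio of 51.5 (95% exact counting interval 13.9 to 431). Cd3d of the same complex had 102 and 0 counts and was at least 33.4-fold lower, against a floor of 3 counts over the group. Nkg7, of cytotoxic lymphocytes, had 114 and 0 counts and was at least 37.3-fold lower. These intervals and bounds cover counting error only. The list's median log2 fold change was -0.32, unchanged with the 2 members without counts in a group set at their bound, and the list was not called (camera adjusted p = 0.159, and 0.023 without the untreated library of line 5, p = 0.264 with an estimated correlation). In wider lists written after the called genes had been seen, 41 of 56 tested macrophage genes rose and 35 of 50 tested T lymphocyte genes fell. Summed over all 56, the macrophage genes were at 460 to 534 CPM without doxycycline and 597 to 935 CPM with it. Most of the sum without doxycycline was Mrc1 alone, at 383 ± 32.7 CPM, which went the other way, to 256 ± 113 CPM (SD, n = 3 each). These libraries also differed in Xist, the RNA of the inactive X chromosome, which had 28 to 42 counts in each library without doxycycline and 0 to 4 in each with it (edgeR adjusted p = 0.00531). The Y-linked Ddx3y was at 87.7 ± 15.8 CPM without and 87.8 ± 25.8 CPM with doxycycline (SD, n = 3 each).

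**Figure D2:**
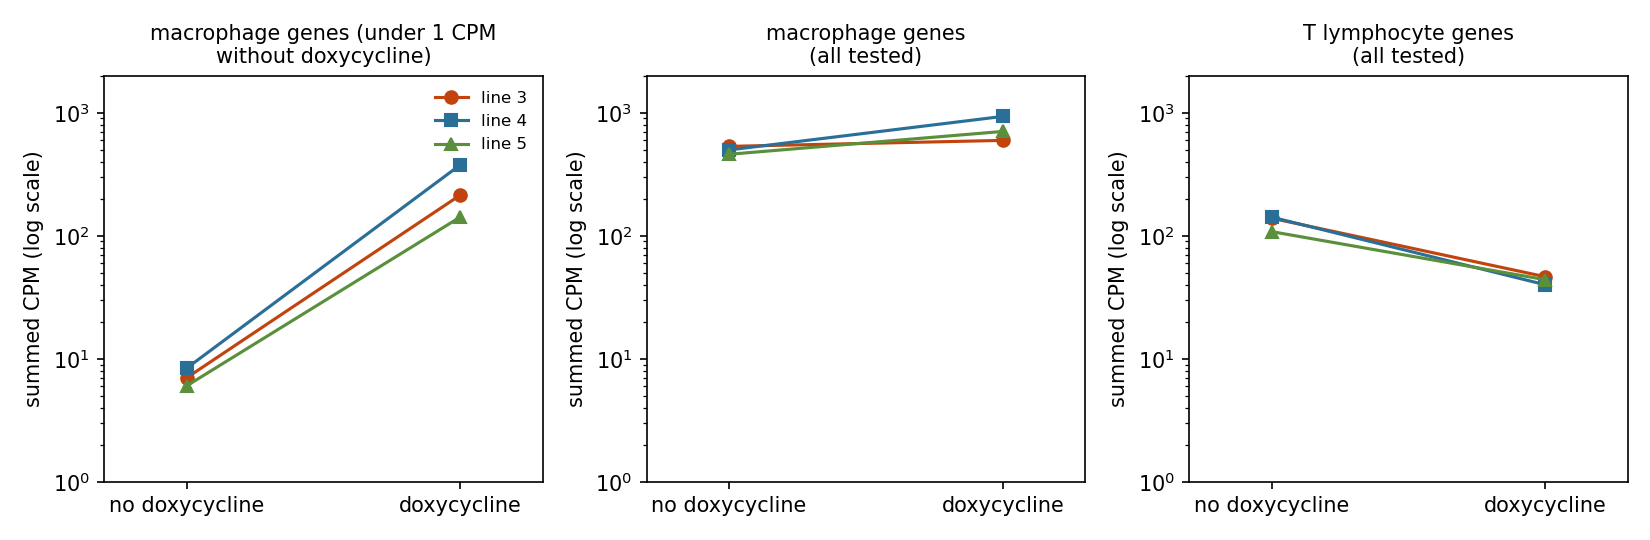
Summed CPM (log axes) of the 39 macrophage genes with a mean under 1 CPM without doxycycline, left, of all 56 tested macrophage genes, middle, and of all 50 tested T lymphocyte genes, right, in the 6 libraries, with a line joining the libraries of each stable line. With doxycycline the 39 genes reached 215, 378 and 142 CPM in lines 3, 4 and 5, a set whose low start favours a rise, while all 56 went from 534, 499 and 460 CPM to 597, 935 and 706 CPM, and the T lymphocyte genes were at 40.03 to 46.5 CPM against 108 to 142 CPM without it. Most of the sum of all 56 without doxycycline was Mrc1, at 383 CPM on average, and 256 CPM with it. In the T lymphocyte sum Tigit was at 17.5 CPM on average without doxycycline and 14.6 CPM with it, while 35 of the 50 genes fell.

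The named genes that fell most were of several kinds. Klf2, a transcription factor of endothelial cells and resting lymphocytes, went from 8.48 ± 0.755 to 1.76 ± 0.163 CPM (log2 fold change -2.26, SE 0.22, edgeR adjusted p = 0.000779). Fosb, an immediate early gene, went from 8.59 ± 1.25 to 1.93 ± 0.415 CPM (edgeR adjusted p = 0.00167). Dhrs9, a retinol dehydrogenase, went from 30.3 ± 2.80 to 9.28 ± 1.63 CPM (log2 fold change -1.71, SE 0.17, edgeR adjusted p = 0.000969). P-selectin (Selp) went from 21.3 ± 2.77 to 5.82 ± 3.02 CPM (edgeR adjusted p = 0.0107), with 14.1% of its exonic bases shared with other annotated genes. Involucrin (Ivl), a component of the cornified envelope of squamous cells, went from 15.4 ± 4.13 to 4.90 ± 2.52 CPM (edgeR adjusted p = 0.037). The transcription factor Nfe2l3, the formin Fmnl1, the neuronal pentraxin Nptx1 and the annotated pseudogene Olfr1372-ps1 had log2 fold changes of -1.62, -1.48, -1.47 and -1.53 (edgeR adjusted p = 0.0139, 0.0243, 0.0082 and 0.0428).

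**Figure D3:**
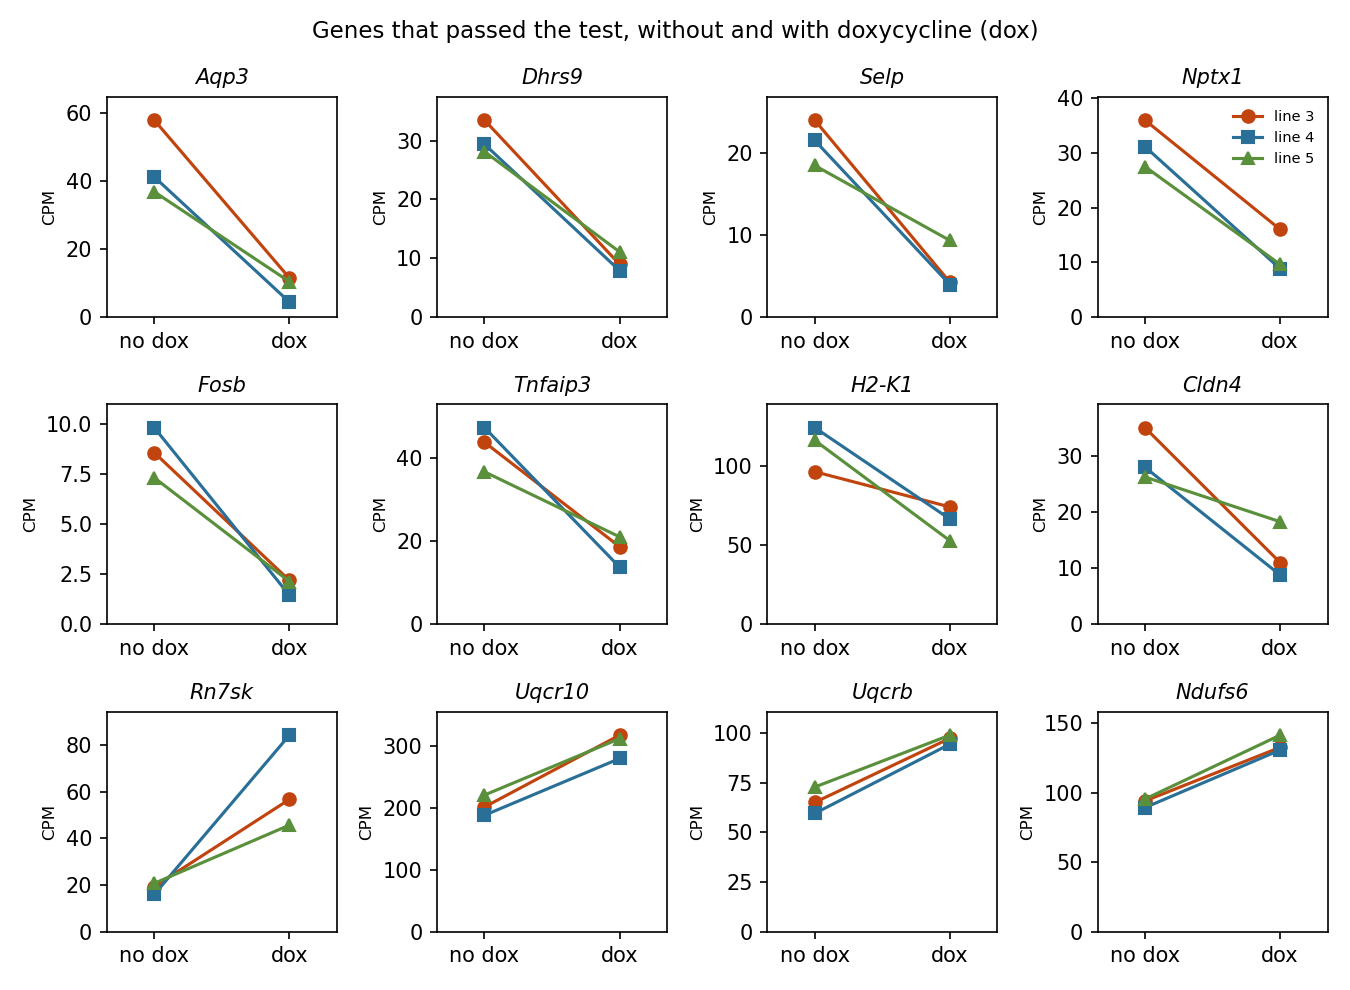
Levels in CPM of 12 genes that passed the test, without and with doxycycline (dox), each point 1 library and each line joining the libraries of a stable line. The upper 8 genes were lower with doxycycline in all 3 lines, as Aqp3 (45.4 to 8.73 CPM on average), and the lower 4 were higher, as Rn7sk (18.7 to 62.2 CPM on average).

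The number of calls depended on single libraries. Leaving out the untreated library of line 3, 4 or 5 gave 89, 117 or 182 genes, and leaving out the treated library of line 3, 4 or 5 gave 1551, 311 or 308. Besides Npm1, 42 of the named genes had passed, and the 3 fits without an untreated library kept 19, 22 and 28 of these calls, against 42, 35 and 27 for the 3 fits without a treated library. All 332 genes differed in the same direction in the 3 lines, and their groups did not overlap. Groups that do not overlap differ in the same direction in every line, and the test favours such genes. Neither result is therefore separate evidence for the calls. Over all genes tested the groups did not overlap for 22.6%, where chance gives 10%. DESeq2 called 720 genes, edgeR 181 when genes of macrophages and lymphocytes were left out before the fit, and edgeR 51 when only genes with at least 5 CPM on average were tested. Of the 332 genes, 254 and 149 were still tested in these last 2 fits, and 181 and 51 kept their call. With the p-values over all genes adjusted over those tested alone, 181 and 64 genes passed. The named genes Ivl, Ndufs6, Olfr1372-ps1, Hist1h1a, Uqcrb, Fos, Uqcr10 and Impdh1 were not among these 181. Their unadjusted edgeR p were 0.000672 to 0.00112, so their calls depended on the macrophage and lymphocyte genes being in the adjustment.

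The question of whether groups of genes moved together was put to 24 fixed lists, of which 23 had enough tested members. By camera with a preset correlation of 0.01 between genes, 6 lists were higher and 6 lower (adjusted p under 0.05). With the correlation estimated from these libraries none of the 12 calls held, and fry, which asks whether the genes of a list move one way on balance, called 0 lists, so the p with an estimated correlation is given with each.

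Genes of energy metabolism and of growth made up the lists that were higher. The nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of 0.32 (camera adjusted p = 1.15e-14, p = 0.0902 with an estimated correlation). Of the 71 tested, 69 were above 0 and 3 rose over all genes tested (27 adjusted over the list alone), and the other 68 did not pass. These 3 were Ndufs6, a subunit of complex I, and Uqcrb and Uqcr10, subunits of complex III, with log2 fold changes of 0.54 (SE 0.11), 0.56 (SE 0.12) and 0.57 (SE 0.13) and edgeR adjusted p of 0.0373, 0.0452 and 0.0474. With the line as a block these became 0.0679, 0.0678 and 0.0656. None of the 3 genes passed with the p-values adjusted without the macrophage and lymphocyte genes. Once each library's trend on transcript length and GC content was removed by offsets, the log2 fold changes of Ndufs6, Uqcrb and Uqcr10 were 0.39 (SE 0.13), 0.29 (SE 0.14) and 0.51 (SE 0.12). Their calls ended (edgeR adjusted p = 0.182, 0.351 and 0.0844), although the fold of Uqcr10 moved by less than its SE. The 8 tested mitochondrially encoded genes had a median of 0.30 (camera adjusted p = 0.0434, p = 0.386 with an estimated correlation), which became -0.01 with the offsets (camera adjusted p = 0.999). None passed over all genes tested or adjusted over the list alone, and mt-Nd2 and mt-Nd4 had log2 fold changes of 0.57 and 0.40 (edgeR adjusted p = 0.205 and 0.359). The 33 genes of ribosome biogenesis and the nucleolus had a median of 0.12 (camera adjusted p = 0.00989, p = 0.145 with an estimated correlation). None passed alone, and Mrto4 and Nip7 had log2 fold changes of 0.51 and 0.47 (edgeR adjusted p = 0.072 and 0.133).

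Of the 34 tested genes of the cell cycle and mitosis, 32 were above 0, with a median of 0.26 (camera adjusted p = 0.00203, p = 0.501 with an estimated correlation). None passed alone, and Pcna, the sliding clamp of DNA polymerases, and cyclin E1 (Ccne1) had log2 fold changes of 0.40 and 0.56 (edgeR adjusted p = 0.181 and 0.205). Nucleotide synthesis had a median of 0.29 over 21 genes (camera adjusted p = 0.000374, p = 0.159 with an estimated correlation), with 1 gene higher and 1 lower over all genes tested (5 and 1 adjusted over the list alone). Impdh1, an enzyme of guanine nucleotide synthesis, fell from 69.2 ± 6.89 to 42.4 ± 7.97 CPM (edgeR adjusted p = 0.0491, and 0.0927 with the line as a block). The 14 tested replication-dependent histone genes had a median of 0.61 (camera adjusted p = 0.00203, p = 0.124 with an estimated correlation). The linker histone gene Hist1h1a was the 1 that passed (4 adjusted over the list alone), from 0.219 ± 0.0234 to 0.760 ± 0.1198 CPM (edgeR adjusted p = 0.044, and 0.097 with the line as a block). Histone genes of a family can share reads.

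The lists that were lower held genes of antigen presentation, hypoxia, epithelium, matrix, glycolysis and RAS output. Of the 14 tested genes of antigen presentation by MHC class I, 5 fell over all genes tested (7 adjusted over the list alone), 9 did not pass, and the median log2 fold change was -0.58 (camera adjusted p = 1.3e-05, p = 0.0917 with an estimated correlation). The class I heavy chain gene H2-K1, whose reads can be shared with other class I genes, went from 113 ± 14.3 to 64.6 ± 10.8 CPM (log2 fold change -0.80, SE 0.16, edgeR adjusted p = 0.0281). The immunoproteasome subunits Psmb8 and Psmb9 and the peptide transporter subunit Tap2 fell too, from 1.301, 1.43 and 1.28 CPM to 0.306, 0.413 and 0.316 CPM (edgeR adjusted p = 0.0314, 0.0322 and 0.0316). Psmb8 and Tap2 share 14.7% and 18.5% of their exonic bases with other annotated genes. The summed level of the T lymphocyte genes fell too, from 108 to 142 CPM without doxycycline to 40.03 to 46.5 CPM with it. The order of the lines differed, with medians of -1.82, -1.67 and -1.26 in lines 3, 4 and 5 for the T lymphocyte genes. For the antigen presentation list they were -0.31, -0.72 and -0.79, and its summed level rose in line 3, from 613 to 657 CPM. The 0.5 CPM added before these ratios shrinks those of genes near 0, and the fitted median of the T lymphocyte genes was -4.22. Their sums went from 139, 142 and 108 CPM to 46.5, 40.03 and 44.0 CPM in lines 3, 4 and 5, with the largest fall in line 4. By medians and by sums, line 5 had the smallest fall of the T lymphocyte genes and the largest of the antigen presentation list. With the line as a block the edgeR adjusted p of H2-K1, Psmb8, Psmb9 and Tap2 were 0.0528, 0.0818, 0.0579 and 0.0668. The 19 tested genes of the hypoxia response had a median of -0.36 (camera adjusted p = 0.000539, p = 0.27 with an estimated correlation). None passed alone, and the growth factor Vegfa and carbonic anhydrase 9 (Car9) had log2 fold changes of -0.47 and -0.64 (edgeR adjusted p = 0.116 and 0.142).

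Of the 24 tested epithelial genes, 22 were below 0, with a median of -0.29 (camera adjusted p = 0.000374, p = 0.154 with an estimated correlation). The tight junction gene Cldn4 fell, from 29.7 ± 4.65 to 12.7 ± 4.96 CPM (log2 fold change -1.23, SE 0.25, edgeR adjusted p = 0.0325), and 2 genes fell adjusted over the list alone. The 23 tested mesenchymal and matrix genes had a median of -0.26 (camera adjusted p = 0.00607, p = 0.116 with an estimated correlation). Over all genes tested 1 of them fell (1 higher and 8 lower adjusted over the list alone). The 20 tested glycolysis genes had a median of -0.25 (camera adjusted p = 0.00753, p = 0.369 with an estimated correlation). None passed alone, and phosphofructokinase Pfkp and the glucose transporter Slc2a1 had log2 fold changes of -0.42 and -0.50 (edgeR adjusted p = 0.176 and 0.186). RAS and ERK output had a median of -0.14 over 23 genes (camera adjusted p = 0.0491, p = 0.326 with an estimated correlation), a call lost with the line as a block (camera adjusted p = 0.0615) and with RLE scaling (camera adjusted p = 0.0512). With the length and GC offsets its median was -0.05 (camera adjusted p = 0.0503). The immediate early gene Fos fell from 9.73 ± 2.36 to 4.39 ± 1.02 CPM (edgeR adjusted p = 0.0452, and 0.0721 with the line as a block), and 2 genes fell adjusted over the list alone.

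The other 11 lists were not called or not tested as lists. In the type I interferon response Zbp1 fell, from 0.684 ± 0.0939 to 0.107 ± 0.0806 CPM (edgeR adjusted p = 0.0311, and 0.0595 with the line as a block). The list's median was -0.12 over 27 genes (camera adjusted p = 0.0809), with 2 genes lower adjusted over the list alone. This list passed in the lower direction without the untreated library of line 4 (camera adjusted p = 0.0276), the treated library of line 4 (0.0131) or line 4 (0.0033), with p = 0.169, 0.0522 and 0.0646 with an estimated correlation. Among 14 tested cytokine and chemokine genes 2 fell, over all genes and adjusted over the list alone: the chemokine Ccl5, from 4.42 ± 0.614 to 0.209 ± 0.176 CPM (edgeR adjusted p = 0.00102), and Tnfaip3, which restrains NF-kappaB signalling, from 42.6 ± 5.42 to 17.8 ± 3.73 CPM (edgeR adjusted p = 0.00503). T and other cytotoxic lymphocytes also express Ccl5, and the summed level of the T lymphocyte genes moved with it, from 108 to 142 CPM without doxycycline to 40.03 to 46.5 CPM with it. That sum understates the fall of most of its genes. With doxycycline 10 of the 50 kept a mean of 1 CPM or more, as Tigit at 14.6 ± 3.19 CPM (SD, n = 3). The median log2 fold change of the 50 was -4.22, and that of Ccl5 was -4.46. The list of cytokines and chemokines had a median of 0.11, a mean of -0.27 and a test in the lower direction (camera adjusted p = 0.0821). Cytosolic ribosomal protein genes had a median of -0.03 over 78 genes (camera adjusted p = 0.197). The line medians were 0.45 in line 3, -0.39 in line 4 and -0.34 in line 5. Without the treated library of line 3 the median was -0.38 (camera adjusted p = 3.57e-19), as it was -0.36 without line 3 (camera adjusted p = 4.79e-17). With an estimated correlation these gave p = 0.147 and p = 0.253. Rplp1 and Rps29 had log2 fold changes of -0.62 and -0.30 (edgeR adjusted p = 0.362 and 0.526). Reads of this family can also align to pseudogenes, which was not tested here, and reads that align to more than 1 place were not counted. The 24 p53 targets had a median of -0.02 (camera adjusted p = 0.735), with Trp53inp1 at -0.78 and Rps27l at 0.49 (edgeR adjusted p = 0.0812 and 0.129, the first being 0.0233 with the line as a block). The tricarboxylic acid cycle had a median of 0.11 over 21 genes (camera adjusted p = 0.192), with Sdhd at 0.37 and Suclg1 at 0.30 (edgeR adjusted p = 0.206 and 0.273).

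The ATF4 and amino acid stress response had a median of 0.01 and a test in the lower direction over 27 genes (camera adjusted p = 0.79), with Vldlr at -0.39 and Ddit4 at -0.56 (edgeR adjusted p = 0.154 and 0.232). Its median was -0.30 without the treated library of line 3 (camera adjusted p = 0.0395) and -0.33 without line 3 (camera adjusted p = 0.0112), but 0.31 without the treated library of line 4 (camera adjusted p = 0.000928) and 0.27 without line 4 (camera adjusted p = 0.00021). With an estimated correlation these 4 gave p = 0.61, 0.593, 0.209 and 0.226. Chaperones and heat shock genes had a median of -0.07 over 19 genes (camera adjusted p = 0.735), with Hspe1 at 0.44 and Hsp90b1 at -0.34 (edgeR adjusted p = 0.164 and 0.276). Cholesterol synthesis had a median of 0.04 over 22 genes (camera adjusted p = 0.735, and 0.0354 with a median of 0.16 without the treated library of line 5, p = 0.137 with an estimated correlation), with Idi1 at 0.39 and Lss at 0.28 (edgeR adjusted p = 0.254 and 0.431). Lung and endoderm lineage genes had a median of -0.09, a mean of 0.16 and a test in the higher direction over 14 genes (camera adjusted p = 0.735), and their 1 gene that rose, over all genes and adjusted over the list alone, was Lyz2, also a gene of macrophages. Endothelial markers had a median of 0.12 and a test in the lower direction over 7 genes (camera adjusted p = 0.997), with Pecam1 at -1.13 and Vwf at 0.77 (edgeR adjusted p = 0.206 and 0.438). With all libraries 4 fibroblast markers could be tested, too few for a test of the list. Another member entered without the untreated library of line 3 or 4, the treated library of line 3 or 5, or line 3. In these 5 fits the median was -0.89 to -0.50, in the lower direction (camera unadjusted p = 3.63e-05 to 0.000979, p = 0.0244 to 0.0757 with an estimated correlation). Thy1, which T lymphocytes also express, was the 1 of the 4 that fell, over all genes and adjusted over the list alone, from 3.01 ± 0.903 to 0.0525 ± 0.0473 CPM (edgeR adjusted p = 0.00102).

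**Figure D4:**
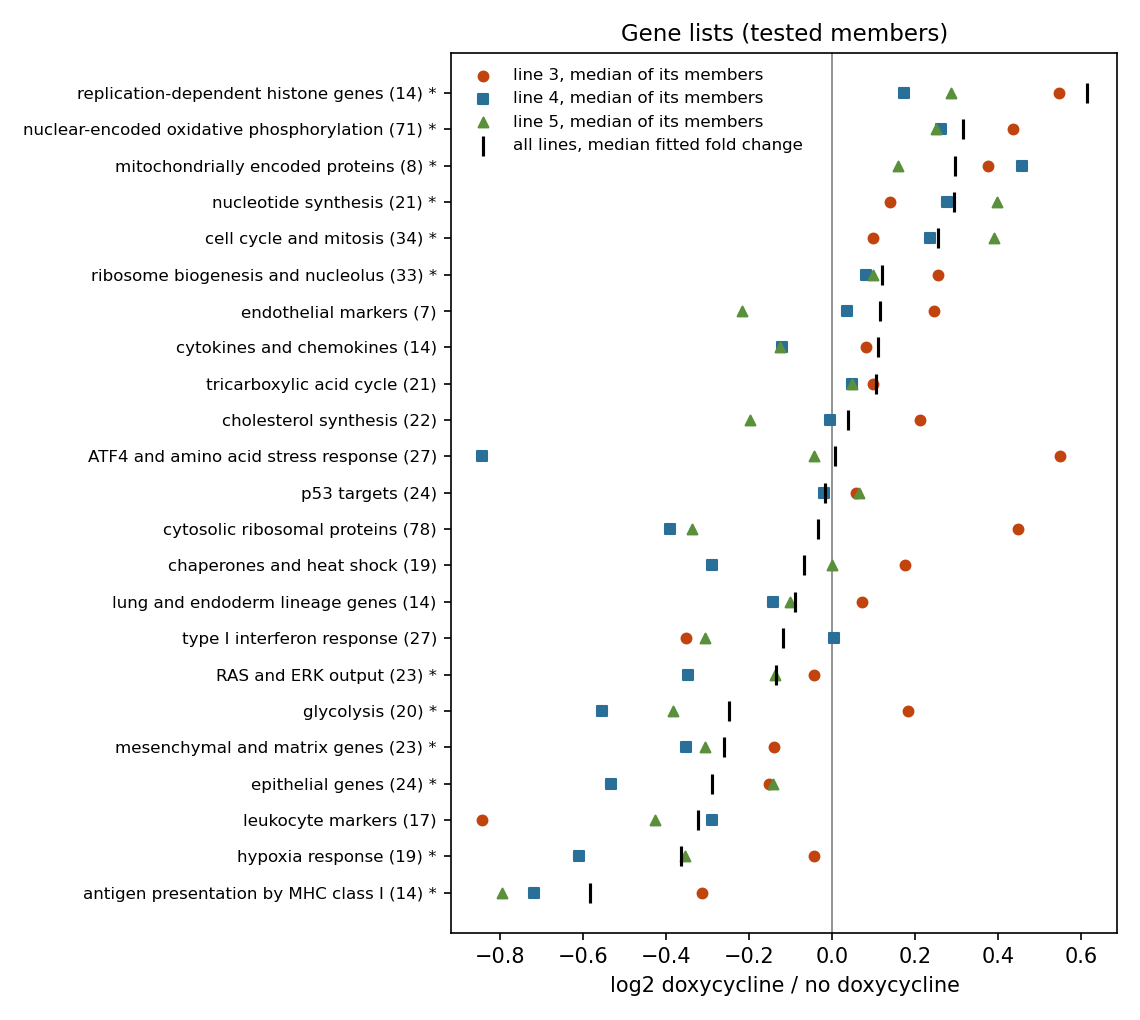
Median log2 ratio of doxycycline to no doxycycline of the 23 tested gene lists, with the number of tested members in brackets. Coloured points are the medians within each line, computed after adding 0.5 to each CPM, black bars the medians of the fitted fold changes, and a star marks a camera adjusted p under 0.05 with the preset correlation. The oxidative phosphorylation genes had line medians of 0.44, 0.26 and 0.25 in lines 3, 4 and 5, while ATF4 genes spread from 0.55 in line 3 to -0.84 in line 4.

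Line 3 stood apart in the relation of its log2 ratio to transcript length, and lines 4 and 5 in that to GC content. The relation to length touches lists of short transcripts such as oxidative phosphorylation, ribosomal protein and histone genes. Across 10189 genes with at least 5 CPM on average, Spearman's rho between the line's log2 ratio and transcript length was -0.469 in line 3, -0.029 in line 4 and 0.059 in line 5, and that with GC content was 0.18, -0.357 and -0.414, a description across genes, which are not independent replicates. In line 3 the 2552 genes with the shortest transcripts had a median log2 ratio of 0.26 and the 2546 with the longest a median of -0.21 (median lengths 1552 and 6330 bases). The share of reads that aligned to more than 1 place was 37.8% in this library and 31.4% to 34.6% in the other 5. With the length and GC offsets 7 further named genes lost their call, namely Cldn4, Fmnl1, Hist1h1a, Impdh1, Ivl, Olfr1372-ps1 and Tap2 (edgeR adjusted p = 0.0726, 0.0512, 0.0724, 0.0685, 0.0507, 0.125 and 0.0588). In this order their log2 fold changes were -1.18, -1.25, 1.74, -0.56, -1.69, -1.42 and -1.81 with the offsets (SE 0.27, 0.27, 0.40, 0.13, 0.36, 0.39 and 0.40). Before, they were -1.23, -1.48, 1.78, -0.71, -1.66, -1.53 and -1.99 (SE 0.25, 0.28, 0.39, 0.16, 0.34, 0.33 and 0.40), so each moved by less than its SE before the offsets, from edgeR adjusted p of 0.0243 to 0.0491. Several lists lost their call, or had a median moved by over 1.5 times, without a single library or line. Ribosome biogenesis, with a median of 0.12 over all libraries, had 0.13 without the treated library of line 3 (camera adjusted p = 0.0526), 0.10 without the untreated one (0.0833) and 0.08 without line 3 (0.165). Mitochondrially encoded genes, at 0.30, had 0.15 without the treated library of line 3 (0.269), 0.14 without the untreated library of line 4 (0.272) and 0.20 without line 4 (0.103). Glycolysis, at -0.25, lost the call at -0.13 without the treated library of line 5 (0.184), -0.08 without line 4 (0.177) and -0.14 without line 5 (0.109). It kept it at -0.16 without the treated library of line 4 (0.043), -0.47 without that of line 3 (1.6e-06) and -0.46 without line 3 (2.41e-07). For these 3 fits camera with an estimated correlation gave p = 0.558, 0.0795 and 0.109. The cell cycle, at 0.26, lost the call at 0.08 without the treated library of line 5 (0.289), 0.09 without the untreated library of line 3 (0.25) and 0.18 without line 5 (0.0709), and was at 0.49 without the treated library of line 3 (1.07e-10). In this last fit camera with an estimated correlation gave p = 0.207. Mesenchymal genes, at -0.26, lost it at -0.30 without line 4 (0.099), and were at -0.41 without the treated library of line 3 (0.000613) and -0.47 without line 3 (0.000267). In these last 2 fits camera with an estimated correlation gave unadjusted p = 0.0411 and 0.0697. RAS and ERK output, at -0.14, lost it at -0.17 without the treated library of line 3 (0.0874), -0.10 without that of line 4 (0.152), -0.09 without the untreated library of line 4 (0.187) and -0.07 without line 4 (0.393). It kept it at -0.25 and -0.08 without the untreated library of line 3 (0.00707) or 5 (0.0445) and at -0.23 without line 3 (0.0143). For these 3 fits camera with an estimated correlation gave p = 0.188, 0.37 and 0.332. The hypoxia response, at -0.36, was at -0.23 without the treated library of line 5 (0.0354), where camera with an estimated correlation gave p = 0.465. The p in brackets are camera adjusted p with the preset correlation.

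The 3 lines were also compared with each other, with treatment held constant. No gene passed in edgeR's quasi-likelihood F test (0 of 14531, smallest adjusted p = 0.868, 667 genes at an unadjusted p under 0.05), and DESeq2's likelihood ratio test called 16. The 6 genes of smallest p with at least 5 CPM on average included Pamr1 and Pdzk1ip1, highest in line 3. Pamr1 was at 10.6 and 11.9 CPM in line 3 without and with doxycycline, 3.96 and 2.61 CPM in line 4 and 4.57 and 3.10 CPM in line 5. Pdzk1ip1 differed by a log2 value of -1.76 between line 4 and line 3 and by -1.20 between line 5 and line 3. The mitotic kinase Plk1 and the cell cycle factor E2f8 had values of 1.01 and 1.43 for line 4 against line 3, and Crisp1 and Gpnmb values of -0.97 and 0.84. All 6 had an edgeR adjusted p of 0.868. The count of genes was 330, 20 or 130 without the untreated library of line 3, 4 or 5, and 0, 0 or 12 without the treated one.

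The response to doxycycline was set side by side for the lines without a test, since each had 1 library per condition. The log2 ratios of lines 4 and 5 correlated across the 10197 genes with at least 5 CPM on average with Pearson's r = 0.638, those of lines 3 and 4 with r = 0.295 and those of lines 3 and 5 with r = 0.234, correlations across genes, which are not independent replicates. Among these genes, a log2 ratio beyond 1 in either direction was found for 169 in line 3, 378 in line 4 and 153 in line 5. The median size of the log2 ratio was then taken over the called genes with at least 5 CPM on average. In line 3, where the least Npm1 remained, it was 0.78, in line 4 it was 1.08 and in line 5 it was 0.79.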

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

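The tests of the macrophage and T lymphocyte genes, of line 3 and of doxycycline itself for the oxidative phosphorylation genes and of the count of genes over other splits, and the estimated correlations without line 3 or with offsets, were chosen only after those results had been seen.

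A first pattern is the appearance of macrophage genes with doxycycline. For RNA or reads from macrophages, 76.8% of the 56 tested genes, short of the 80% set as its limit, were higher in every treated library than in every untreated one, a share that restates the pattern. These were 38 of the 39 genes under 1 CPM without doxycycline and 5 of the 17 at 1 CPM or more without it, while Mrc1, the list's most abundant gene, was not among them at 383 ± 32.7 CPM without and 256 ± 113 CPM with doxycycline (SD, n = 3 each), and 9 of the 56 were also in the fixed lists. The log2 ratio of line 4 to line 3 varied over the 29 called macrophage genes with at least 50 counts on average with doxycycline, a minimum set after the prediction, with an SD of 0.261, against 0.531 over 69 other genes that rose, so that a single admixed source remains a candidate explanation. Induction in the KP cells, in step with the loss of Npm1 or not, cannot be told apart from it, because no value is per cell and each line had 1 treated library: the list's sum was 597, 935 and 706 CPM in lines 3, 4 and 5 with doxycycline (log2 ratio of line 3 to line 4 -0.647; mean 746 CPM, and 498 CPM without it), and that of the 39 genes was 215, 378 and 142 CPM, neither in the order of the loss of Npm1, which was largest in line 3 and smallest in line 5.

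A second pattern is the loss of T lymphocyte genes with doxycycline. RNA or reads from lymphocytes of another animal in the libraries without doxycycline may account for it but cannot be told apart from other sources, since its sign, Xist, had been seen before the test: Xist, which cells with Y-linked transcripts would not be expected to express, had at least 28 counts in each of them and at most 4 in a treated library, while the 88.0% of the 50 tested genes that were higher in all 3 of them restates the pattern. Of the 3 tested B lymphocyte genes 2 fell, and the summed level of the 3 was 2.96 to 7.603 CPM without doxycycline and 0.529 to 0.842 CPM with it. Expression by the KP cells cannot be told apart, since no value is per cell, and the list's mean sum was 130 CPM without and 43.5 CPM with doxycycline, where 10 of the 50 genes had a mean of 1 CPM or more, such as Tigit at 14.6 ± 3.19 CPM, and 6 of the 50 were also in the fixed lists. An effect of Npm1 on these genes was not tested apart from the treatment.

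The last pattern is the higher level of nuclear-encoded oxidative phosphorylation genes (p = 0.0902 with an estimated correlation). Removal of each library's trend on transcript length and GC content left a median log2 fold change of 0.23 of the 0.32 before (camera adjusted p = 5.48e-09, p = 0.0355 with an estimated correlation). This argues against that trend, as measured on the longest annotated transcript of each gene, as the whole cause of the list's median. The calls of its 3 single genes ended, and a trend on the length of the transcripts expressed was not tested. Without line 3 the median was 0.24 (camera adjusted p = 1.35e-07, p = 0.295 with an estimated correlation), which argues against the treated library of line 3 as the whole cause. Doxycycline, which may act on mitochondrial translation, cannot be told apart from the loss of Npm1, as no library had the drug without a hairpin against Npm1, and 69 of 71 genes were above 0.

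With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split (1 of 10 with as many) gave 332 genes and the highest other split 0, and for the lists the real split (1 of 10 with as many) gave 12 and the highest other split 11. Every other split has treated and untreated libraries in both groups, so any difference between them adds to the spread and lowers the count of genes. The 0 genes therefore decide nothing about chance. Of the other 9 splits, 3 also put the libraries of each line in different groups, and these gave 0 genes and 7, 9 and 11 lists.

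Several lists and genes were picked out because lines moved in opposite directions, a difference that was not tested since each line had 1 library per condition. In log2 units, the lowest and highest line medians were -0.39 and 0.45 for cytosolic ribosomal proteins, -0.56 and 0.18 for glycolysis, -0.02 and 0.065 for p53 targets, -0.84 and 0.55 for the ATF4 response, -0.29 and 0.18 for chaperones, -0.35 and 0.005 for the interferon response, -0.13 and 0.082 for cytokines, -0.20 and 0.21 for cholesterol synthesis, -0.14 and 0.072 for lung lineage genes and -0.22 and 0.25 for endothelial markers. For single genes they were -0.72 and 0.29 for Rps29, -0.004 and 0.71 for Idi1, -0.10 and 0.54 for Lss, -0.059 and 0.86 for Vwf, -0.52 and 0.15 for Pamr1, -0.29 and 0.59 for Pdzk1ip1 and -0.18 and 0.35 for E2f8. None of these 7 genes had passed the test of doxycycline.

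Reads outside the comparisons were picked out where a treated library lay above all 3 untreated ones. Reads without a gene made up 4.47% in line 4, ambiguous reads 3.26% in line 3 and 3.14% in line 4, and reads with more than 1 alignment 37.83% in line 3.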

How the results depend on the processing

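The offsets for transcript length and GC content, the minimum of 5 CPM, the fit without macrophage and lymphocyte genes the list tests on DESeq2 and limma-voom values and the estimated correlations with a library or line left out or with the offsets, and the p-values of all genes adjusted over fewer genes, were chosen after seeing the data. Npm1 kept its direction under all 16 alternatives and its call under 14, with log2 fold changes of -3.63 to -2.55; leaving out the untreated library of line 3 or line 4 as a whole ended the call.

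The 332 genes became 1052 without a filter on low counts (a fit with infinite prior degrees of freedom, against 6.29), 720 with DESeq2, 593 and 121 at adjusted p of 0.1 and 0.01, 157 against a log2 fold change of 0.5, 51 with a minimum of 5 CPM and 181 (68 higher, 113 lower) without macrophage and lymphocyte genes (98 and 73 of the 332 were still tested and lost the call in these last 2 fits), and ranged from 62 (without line 4) to 1551 (without the treated library of line 3) with a library or line left out; apart from the fewer genes, samples or stricter limits tested, the cause was not tested. The replicate block gave 243, and RLE scaling 332. The 12 lists became 0 with an estimated correlation and 0 with fry; the other 16 alternatives gave 10 to 15. RLE scaling moved the median gene by 0.006 (log2). The line comparison gave 240 genes without a filter, 16 with DESeq2, and 0 to 330 with a library left out, where a line keeps a single library that is assumed to vary like the others. The called genes had the same direction in the 3 lines with RLE scaling, the replicate block, limma-voom and the offsets. Without a filter 93.3% did and with DESeq2 99.9%. This share, which the tests themselves favour, was not computed under the other alternatives.

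No named gene reversed. Of 42 called ones besides Npm1, 31 kept the call with the replicate block and 32 with the length and GC offsets. List medians that changed sign were those of mitochondrially encoded genes with the offsets (-0.01, and -0.017 with the replicate block too), p53 targets (0.017 with the offsets), the ATF4 response (-0.006 without a filter, -0.081 with the replicate block, -0.072 with limma-voom, -0.003 with offsets and replicate block), cytokines (-0.004 with offsets and replicate block) and lung lineage genes (0.046 with offsets, 0.031 with the replicate block too); the cause was not tested. With a library or line left out, medians ran from -0.38 to 0.14 for cytosolic ribosomal proteins, -0.081 to 0.097 for p53 targets, -0.33 to 0.31 for ATF4, -0.14 to 0.007 for chaperones, -0.12 to 0.16 for cholesterol synthesis, -0.13 to 0.034 for lung lineage genes and -0.072 to 0.30 for endothelial markers. With the offsets the cytosolic ribosomal proteins (median -0.14, camera adjusted p = 0.000114), interferon response (0.0333) and cytokines (0.0108) passed (p = 0.521, 0.298 and 0.041 with an estimated correlation). Among called lists the replicate block ended the call of RAS and ERK output, and beside the genes given with their results it changed no other call of a list or gene named by the rule; of the 332 genes it kept 226. Depth limits the genes near 0: 3 counts are 0.11 to 0.123 CPM.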

Other observations

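The lists of mitochondrial ribosomal protein, DNA replication and hemidesmosome genes were written after the called genes had been seen, and members that had passed prompted them. Their tests were set before their own results were seen, except the estimated correlations without a line or with offsets.

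Of 35 tested DNA replication genes 3 rose with doxycycline and 32 did not pass, and the list's median log2 fold change was 0.39 (camera adjusted p = 1.61e-09, p = 0.197 with an estimated correlation). Prim1, the primase subunit, went from 69.5 ± 3.04 to 123 ± 21.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.0169), the fork protection factor Tipin from 53.7 ± 2.54 to 96.1 ± 21.4 CPM (edgeR adjusted p = 0.0265) and the clamp loader subunit Rfc3 from 46.5 ± 2.52 to 67.0 ± 2.15 CPM (edgeR adjusted p = 0.0454, and 0.0914 with the line as a block). With the length and GC offsets Tipin and Rfc3 lost the call (edgeR adjusted p = 0.1 and 0.0665), with log2 fold changes of 0.66 (SE 0.17) and 0.45 (SE 0.10) against 0.84 (SE 0.16) and 0.53 (SE 0.12) before. Of the 35 genes, 33 were above 0. Mitochondrial ribosomal protein genes had a median of 0.26 over 75 genes, 70 of them above 0 (camera adjusted p = 6.63e-12, p = 0.185 with an estimated correlation). Of these 3 rose. Mrpl13 went from 139 ± 10.98 to 228 ± 30.7 CPM (edgeR adjusted p = 0.0276, and 0.0588 with the offsets, where its log2 fold change was 0.73, SE 0.16, against 0.71, SE 0.14, before). Mrpl20 and Mrpl42 had log2 fold changes of 0.57 (SE 0.12) and 0.57 (SE 0.12), and lost the call with the line as a block (edgeR adjusted p = 0.0422 and 0.0311, and 0.059 and 0.0611 with the block). With the offsets Mrpl20 was at 0.41 (SE 0.11, edgeR adjusted p = 0.118).

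Of 25 tested genes of hemidesmosomes and squamous epithelium, 7 fell over all genes tested and 23 were below 0, with a median of -0.44. The integrin Itgb4 of the hemidesmosome went from 58.7 ± 9.39 to 26.9 ± 3.89 CPM (edgeR adjusted p = 0.00503), the laminin chain Lamb3 from 86.1 ± 14.3 to 44.8 ± 11.7 CPM (edgeR adjusted p = 0.0366) and the transcription factor Klf4 from 60.0 ± 3.76 to 31.3 ± 10.7 CPM (edgeR adjusted p = 0.046). With the offsets Lamb3 and Klf4 lost the call (edgeR adjusted p = 0.0764 for both), with log2 fold changes of -0.73 (SE 0.17) and -0.84 (SE 0.20) against -0.94 (SE 0.20) and -0.94 (SE 0.21) before. Outside these lists, the fatty acid binding protein Fabp5 rose from 128 ± 7.18 to 228 ± 33.5 CPM (edgeR adjusted p = 0.0137) and Afp, which encodes alpha-fetoprotein, from 47.6 ± 4.00 to 88.3 ± 23.6 CPM (edgeR adjusted p = 0.0322), and the cell cycle inhibitor Cdkn2d fell from 55.7 ± 3.81 to 23.5 ± 5.68 CPM (edgeR adjusted p = 0.00469). These genes were chosen after their values were seen.

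For the hemidesmosome and squamous genes, camera gave p = 0.0249 with an estimated correlation and p = 6.07e-10 with the preset one, and p = 0.122 with an estimated correlation without line 4. The list was written because members had passed in these libraries, so this test decides nothing about a change of the group against other genes. For the DNA replication genes the median without line 3 was 0.40 (camera adjusted p = 4.66e-11, p = 0.157 with an estimated correlation) against 0.39 over all lines. That value decides nothing either, since line 3 had the smallest line median. For the mitochondrial ribosomal proteins the median was 0.24 after the trends on transcript length and GC content were removed, against 0.26 before, so little of the median went with those trends. After the removal camera gave an adjusted p of 7.45e-10 and p = 0.0469 with an estimated correlation, against p = 0.185 with an estimated correlation before. This list, too, was written because members had passed, so these p decide nothing about a change of the group against other genes.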
